A study of Bos taurus with 12 samples.

How the data were processed

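Genomic DNA from 12 bull sperm samples was profiled by enzymatic methylation sequencing (EM-seq), in which enzymes rather than bisulfite convert unmethylated cytosines before sequencing. The labels put 6 samples in a low daughter fertility group and 6 in a high daughter fertility group, and name no batch, age or pairing. The submitters' processing notes name Trimmomatic, Bismark, methylKit and the cattle genome build ARS-UCD1.2, with no versions, roles or settings. Read trimming, alignment and methylation calling were therefore taken as the authors left them.

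The files analysed were 2 tables of the authors' own comparison of the groups, with 17730 single CpG sites and 7290 windows of 500 bp. Window starts lay on a 100 bp grid, so neighbouring windows overlap and share CpG sites, and 436 windows had the same difference and p as another window of their chromosome. These windows are called tiles below. Each locus had a p-value, a q-value and a methylation difference in percentage points, all computed by the authors and deposited under the column names that methylKit uses. The adjustment behind the q-values is not stated in the labels or headers. The authors' q-value lay below the p-value of the same locus for 18.5% of sites and 68.7% of tiles, so these q-values are not Benjamini-Hochberg values over the listed loci. The authors' difference is signed, but neither the file headers nor the labels say which group was subtracted from which. Differences are therefore described as positive or negative as listed, and no sign was assigned to high or low fertility. The authors also deposited, for each locus, the closest annotated feature (exon, coding sequence, untranslated region, intron or CpG island), its position and the distance to it.

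Per-sample methylation levels and read coverage were not analysed here, so the depth behind each value is unknown, and no value could be given a spread between samples. For the same reason no new test between the groups was run, no sample was left out in turn, no regrouping of the samples was counted and no coverage minimum was changed. A q-value below states the result of the authors' test. Chromosomes 2, 3, 4, 12, 23 and 27 in the site table, and 12, 23 and 27 in the tile table, were not analysed here. Shares of listed loci and comparisons between chromosomes hold for the loci analysed, which are not taken to be all loci tested.

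The plan made before the data were examined was to count the authors' values by direction at the loosest q and difference met by every listed locus. Both tables turned out to list loci with q up to 0.877 for sites and 0.600 for tiles and with differences near 0, so that rule takes every locus. All listed loci were counted by sign, and a locus was called at q below 0.05 and an absolute difference of at least 10 points, the thresholds that the same plan set for count data. Called loci of 1 sign that overlapped or adjoined (gap of 0 bp) were merged into regions. After the data were seen, calls were also joined over gaps of up to 100 kb into blocks, to describe how they cluster.

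Genes were taken from the Ensembl identifiers and full names that the authors' annotation pairs with each locus. Among sites, 11035 loci named a gene (3167 genes, of which 2697 had a full name), 4275 had a CpG island as their closest feature and 2420 named only a transcript. Among tiles these were 3318 loci (540 genes, 463 with a full name), 2932 and 1040. Loci with an island or a transcript only were assigned to no gene. A locus was near a gene when the annotated feature lay within 10 kb. The reference gene table used here belongs to a later assembly, ARS-UCD2.0, and was used only for symbols. It matched 531 of the 535 genes carrying an NCBI number in the site table and 106 of the 107 in the tile table.

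The named genes follow a rule fixed before the data were examined. For tiles and for sites separately it takes the 10 largest positive and the 10 largest negative differences among called loci near a gene with a name, 1 locus per gene. It adds the 5 genes with the most separate called regions and up to 4 called members of each of 15 gene lists. Of the 145 genes near a called site 34 had no name, as did 6 of the 12 near a called tile, and these were skipped in the first part. Not every locus that the rule takes is described.

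Counts of signs were described with exact binomial tests and exact 95% intervals, which treat loci as independent although neighbours are not. Shares of called loci were compared by 2-sided Fisher exact tests for annotated features and by chi-square tests for chromosomes (Fisher exact test where an expected count was below 5), the latter on merged listed regions, which are not independent either. Gene lists were tested by 1-sided Fisher exact tests on genes, against all genes with a listed locus within 10 kb. P-values were adjusted by the Benjamini-Hochberg method within each family. The 15 lists hold 568 genes. Correlations between tables are Spearman correlations across loci, which are not independent replicates. Intervals in the closing section come from 2000 bootstrap draws of blocks or of 10 kb bins. Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9 were used. The merging and list tests were tested on simulated data. All 200 planted regions were found. For the comparison of gene lists over single sites (2362 background genes), 0 of 1500 list tests passed with random calls, and a list whose members were made 8 times as easy to call passed in 93 of 100 simulated sets. That list was the one of long axon and synapse genes, with 27 members near a listed site. The other lists had at most 10 such members, so this rate does not hold for them.

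Alternatives tried were q below 0.01 and below 0.001, minimum differences of 20 and 30 points, autosomes only, merging gaps of 500 and 1000 bp, merged regions in place of tiles, 1 site per gene, a CpG within 500 bp of a tile, distances of 2 and 50 kb to a gene, and sites in place of tiles for the gene lists. Added after the data were seen were a gap of 100 kb, leaving out the block with the most calls, 1 vote per block, counting both strands of a CpG once, subtraction of the median of uncalled loci, groups of listed loci joined over 1 kb, and, for distances to genes, autosomes only. Leaving out the block with the most calls was also applied to distances to genes and to chromosomes, and the grouping over 1 kb to chromosomes.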

Results

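Sperm DNA of 12 bull samples was profiled by whole-genome enzymatic methylation sequencing to ask how sperm methylation relates to the fertility of a bull's daughters. The samples fell into 6 with low and 6 with high daughter fertility. The data were 2 tables comparing the groups, one of 17730 single CpG sites and one of 7290 tiles of 500 bp, on the ARS-UCD1.2 build of the cattle genome. The depth of each sample is unknown here and no replicate values lie behind the numbers below, so no spread between samples can be set beside them. A positive or a negative sign is the sign as listed, since the group that was subtracted is not stated.

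Single CpG sites that differed between the groups mostly had a negative difference, and many lay in a few stretches of the genome while the rest were scattered. Joined over gaps of up to 100 kb, the 5 blocks with the most calls together held 46.1% of called sites, and 299 of the 354 blocks had 1 called site. By the authors' deposited table a total of 1053 sites (5.94% of those listed) were called at q below 0.05 and at least 10 points of difference. Of these, 848 were negative and 205 positive, with a median difference of -15.1 points. In total 338 called sites differed by at least 20 points and 66 by at least 30 points. On autosomes 605 sites were called, and the other 448 lay on the X chromosome, which has 23.8% of the listed sites.

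The largest negative differences near named genes fell on genes of varied function. By the authors' deposited table the lowest value of all called sites was -50.6 points (q = 1.29e-09), at position 23018619 of chromosome 6. This site lies 2478 bp from a 5′ untranslated region of B cell scaffold protein with ankyrin repeats 1 (ENSBTAG00000015297), a signalling adaptor of B cells, and is annotated to its promoter. The second lowest within 10 kb of a named gene, in the authors' deposited table, was an intronic site of fibrillin 2, a component of extracellular microfibrils, at -46.1 points (q = 8.78e-08, chromosome 7, position 25559761). An intronic site of phosphatase and actin regulator 2 stood at -40.0 points (q = 3.47e-05, chromosome 9, position 81102724) in the authors' deposited table. A site 6287 bp downstream of fatty acid binding protein 2, an intestinal lipid carrier, was listed at -37.8 points (q = 4.01e-13, chromosome 6, position 5963827) by the authors' deposited table, although only 2 of the 4 called sites near this gene were negative. A promoter site of claudin 20, a tight-junction protein, lay 411 bp from the coding sequence and was listed at -36.4 points in the authors' deposited table. A site at a zinc finger gene, ENSBTAG00000037710, lay in its promoter, 3879 bp from the 5′ untranslated region, at -35.0 points (q = 2.81e-07) in the authors' deposited table, and 6 of the 7 called sites near that gene were negative. Further negative sites, in the authors' deposited table, lay 1304 bp downstream of glutamate ionotropic receptor kainate type subunit 1 (-34.1 points), in an intron of CFAP20 domain containing (-33.6 points) and in an intron of pregnancy-associated glycoprotein 14 (-31.3 points), of a family of proteins made by the trophoblast.

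Of the 10 genes with the largest positive differences, 8 had them in an intron. An intronic site of contactin 3, a neuronal adhesion protein, stood at 39.3 points (q = 3.17e-08, chromosome 22, position 27303005) in the authors' deposited table. Intronic sites of otogelin like (38.9 points, q = 1.57e-07) and of ubiquitin like modifier activating enzyme 6 (37.2 points, q = 8.05e-11), which starts the ubiquitin cascade, followed in the authors' deposited table. ATP binding cassette subfamily G member 8, a sterol transporter, had an intronic site at 36.9 points (q = 5.51e-05) in the authors' deposited table. Intronic sites of kinesin family member 26B (32.5 points), parkin RBR E3 ubiquitin protein ligase (32.0 points), basonuclin 2 (31.1 points) and tumor protein p63 regulated 1 (30.2 points) were also called in the authors' deposited table. The 2 promoter sites of this group were those of extended synaptotagmin 3 (31.1 points, 7162 bp from its 5′ untranslated region) and of phospholipase A2 group IVA (28.0 points, 6541 bp from an exon), the enzyme that releases arachidonic acid, in the authors' deposited table. Of these 10 genes, kinesin family member 26B had 2 called sites and the others had 1 each.

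The highest difference of all called sites belonged to no named gene. It was 58.5 points (q = 9.35e-21) at position 391927 of chromosome 1, 41538 bp from ENSBTAG00000006648, in the authors' deposited table. This site was singled out after its values were seen.

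The genes with the most separate called regions of sites were mostly on the X chromosome. Near ENSBTAG00000038660, ENSBTAG00000051616 and ENSBTAG00000037550, which have no functional name, 36, 21 and 17 separate regions were called. These genes all lie in 1 block of calls, from position 123850767 to 124081655. Merged regions of called sites were at most 3 bp long, so such a count is close to a count of CpG sites. Vesicle associated membrane protein 7, a protein of vesicle fusion, had 16 regions from 17 called sites, all intronic and all negative. Their lowest difference was -19.96 points (q = 0.000219, chromosome X, position 35330211) in the authors' deposited table. On chromosome 21, ENSBTAG00000051425 had 13 regions of 1 site each, 5 negative and 8 positive.

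**Figure D1:**
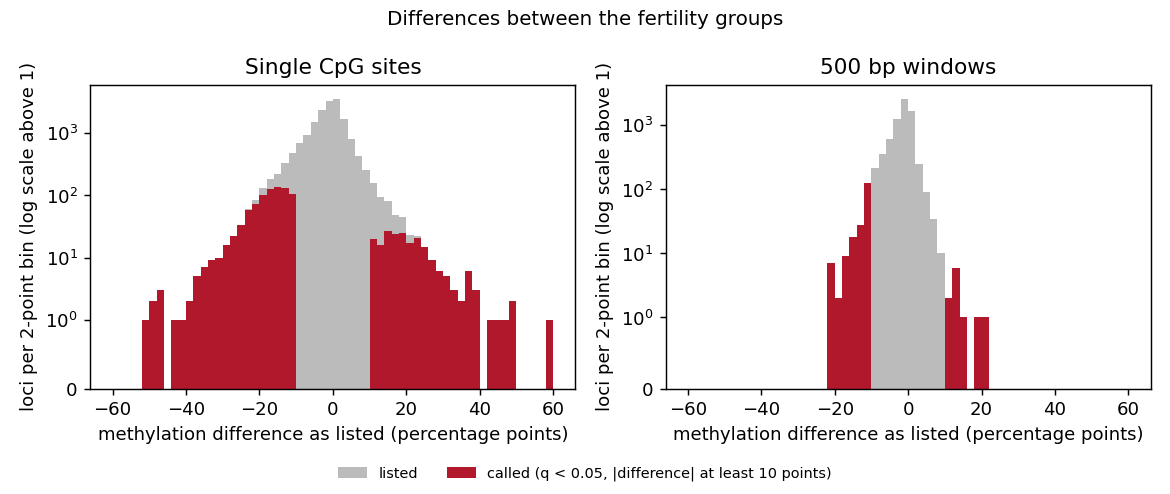
Number of loci (log scale above 1) in 2-point bins of the methylation difference as listed, for single CpG sites and for tiles of 500 bp; grey bars are all listed loci and red bars those called. Called loci lie more often on the negative side, with 848 of 1053 sites and 192 of 203 tiles.

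The tiles, which combine the CpG sites of a window, gave few large differences and these were almost all negative. By the authors' deposited table a total of 203 tiles (2.78% of those listed) were called, 192 of them negative and 11 positive, and they merged into 63 regions, 59 negative and 4 positive. Joined over gaps of up to 100 kb they formed 29 blocks. Smaller differences with q below 0.05 were common, with 5236 tiles (71.8%) in the authors' deposited table and a median absolute difference of 2.42 points among them. Of these tiles, 441 had an unadjusted p of 0.05 or more in the authors' deposited table, since the q listed can lie below p, and no called tile or site was among them. For sites the corresponding count was 1438 (8.11%). At differences of 5 to 10 points, 100% of tiles but 9.33% of sites had q below 0.05. Whether the authors' test allowed for variation between samples is not stated in the labels or headers. A small q is therefore not read as agreement between samples.

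Of named genes, 6 had a called tile within 10 kb, all negative. The lowest was a tile 1135 bp downstream of olfactory receptor 4C6-like, of the odorant receptor family, at -20.9 points (q = 3e-46, chromosome 15, positions 1092801 to 1093300) in the authors' deposited table. The lowest tile anywhere was -21.3 points, on chromosome 16 at positions 11333301 to 11333800, and 589785 bp from the closest feature in the authors' deposited table. A promoter tile of GLIS family zinc finger 3, a transcription factor, was listed at -13.9 points (q = 8.63e-31, chromosome 8, positions 40569401 to 40569900) in the authors' deposited table. Intronic tiles were called in septin 10 (-12.4 points, q = 4.64e-25), a filament protein of the cytoskeleton, and in phosphodiesterase 5A (-10.3 points, q = 5.03e-60), which breaks down cyclic GMP, in the authors' deposited table. The last of the 6 were glycine-N-acyltransferase (278 bp downstream, -11.2 points, q = 2.85e-22) and carbonic anhydrase 10 (intron, -10.0 points, q = 2.6e-21) in the authors' deposited table. No positive tile had a named gene within 10 kb as its closest feature. Distances to genes beyond the closest feature were not measured. Among unnamed genes, ENSBTAG00000052622 on chromosome 14 had 19 called tiles in 6 regions, with a lowest value of -15.1 points (q = 1.3e-48) inside an intron in the authors' deposited table. ENSBTAG00000051816 on chromosome 18 had 6 called tiles in 2 regions, down to -15.0 points (q = 7.28e-31) in the authors' deposited table.

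The blocks of called loci overlapped in part between the tables. Of the 29 tile blocks 10 overlapped a site block, and these held 135 of the 203 called tiles (66.5%), while 9 of the 354 site blocks overlapped a tile block, with 513 of the 1053 called sites (48.7%). The block with the most calls ran from position 123850767 to 124081655 of the X chromosome and held 332 called sites, 325 of them negative, among 2364 listed. The tiles gave a block at positions 123863701 to 124065200 with 45 called tiles, all negative. On chromosome 14 positions 13602401 to 13633500 held 23 called tiles and positions 13764501 to 13806000 held 26, all negative, and the site blocks there had 35 of 37 and 13 of 16 called sites negative. On chromosome 21, 42 of 47 called sites between positions 32902968 and 33028975 were negative. A block of 23 negative tiles on chromosome 6, at positions 5434401 to 5457400, lay at least 287653 bp from the closest annotated feature, a CpG island. On chromosome 1 the signs were mixed, with 24 negative and 23 positive sites between positions 214788 and 502455, and the 10 called tiles between 327701 and 379700 were all positive. These 10 tiles and 1 tile on chromosome 19, at 0 bp from a CpG island, made up the positive tiles. In the authors' deposited table the highest of them was 20.8 points (q = 2.84e-58), 28712 bp from ENSBTAG00000006648.

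**Figure D2:**
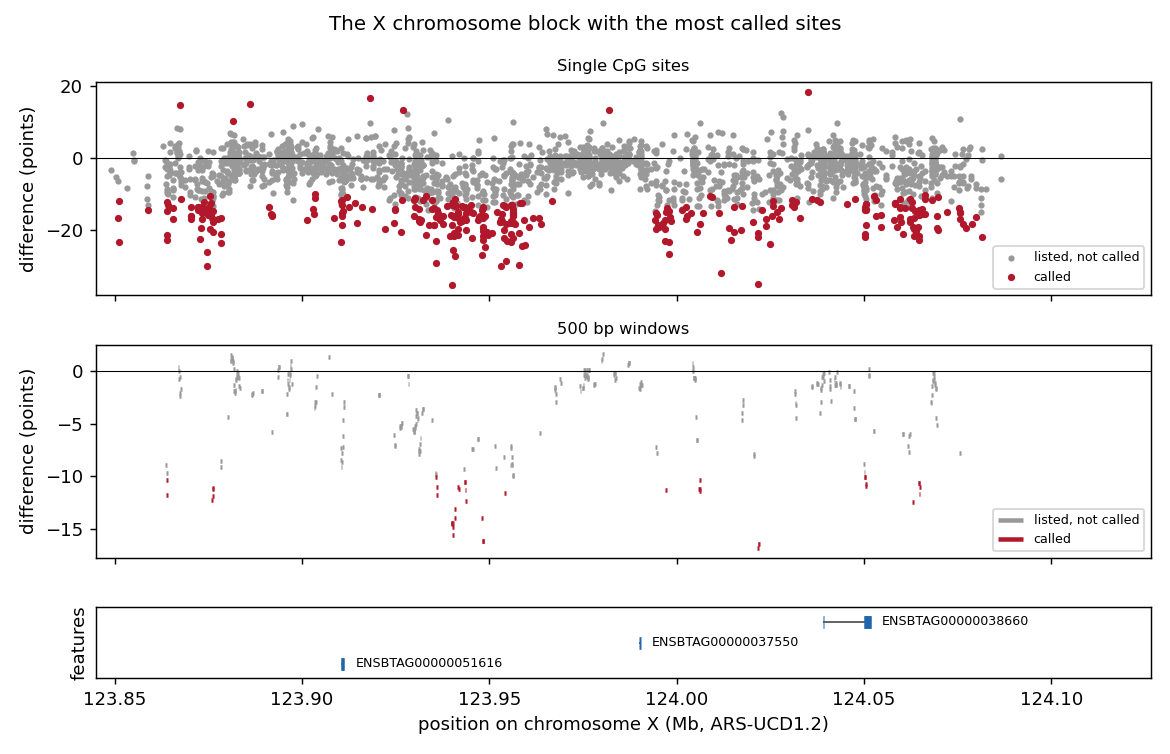
Methylation difference in percentage points as listed, against position on the X chromosome in Mb (ARS-UCD1.2), for single CpG sites and tiles; red marks are called, grey marks listed but not called, and blue boxes the features listed as closest to a locus. Calls form separate groups with stretches near 0 between them, and 325 of the 332 called sites are negative.

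Negative differences outnumbered positive ones in both tables. They made up 80.5% of called sites (exact 95% binomial interval 78.0 to 82.9%; binomial p = 2.27e-93) and 94.6% of called tiles (90.5 to 97.3%; p = 7.57e-44). Neighbouring loci are not independent, and these values describe the lists. With 1 vote per block of calls joined over 100 kb, an alternative chosen after seeing the data, 222 of the site blocks were mostly negative and 123 mostly positive (64.3%, interval 59.0 to 69.4%), with 9 tied. The same count for tiles gave 27 negative and 2 positive blocks (93.1%). On autosomes 68.6% of called sites were negative, and with 1 site per gene near a call 60.7% were. At 30 points or more the share was 62.1% of 66 sites, which did not pass the binomial threshold. Over all listed loci, 61.2% of sites and 71.6% of tiles with a difference other than 0 were negative.

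The 2 tables, which come from the same samples, mostly had the same sign at called tiles. Of 2744 tiles with a listed CpG site inside, 78.5% had the sign of the mean difference of their sites, and the Spearman correlation was 0.67 across these tiles. Among the 102 called tiles with a listed site, 100 had the same sign, and 82 (80.4%, exact 95% interval 71.4 to 87.6%) held a called site. A tile combines the CpG sites inside it, so agreement in sign is partly built in. Called tiles also overlap, and the interval treats them as independent. Of the 2642 tiles that were not called, 17.7% held a called site. The strands of a single CpG give a further comparison, since both were listed for 1825 CpGs. Among the 285 with a call on at least 1 strand, the difference had the same sign on both strands in 239 (83.9%), and both strands were called in 51. Over all 1825 CpGs, 62.9% agreed in sign, against 56.8% if the strands were independent, and the Spearman correlation between strands was 0.32. No such chance share was computed for the 285 CpGs with a call, and called sites are mostly negative.

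Calls were less frequent close to genes over the whole lists but not on autosomes. Among loci whose closest feature names a gene, 314 of 6045 listed sites within 10 kb (5.19%) were called, against 443 of 4990 (8.88%) farther away (odds ratio 0.562, 2-sided Fisher exact test p = 3.72e-14). For tiles these shares were 2.43% and 6.01% (odds ratio 0.390, Fisher exact test p = 5.30e-07). With loci grouped over 1 kb, also chosen after seeing the data, the odds ratios were 0.698 for sites and 0.204 for tiles (Fisher exact test p = 0.00201 and 1.81e-05). A group counted as called, or as near, when any of its loci was, so group size affects both. On autosomes 4.19% of sites within 10 kb and 4.51% farther away were called (odds ratio 0.927, Fisher exact test p = 0.527), and for tiles the odds ratio was 0.926 (Fisher exact test p = 0.792). Without the block of each table with the most calls, both alternatives chosen after seeing the data, the odds ratios were 0.798 for sites and 0.788 for tiles (Fisher exact test p = 0.0251 and 0.370). At 50 kb the direction turned, with odds ratios of 1.06 and 1.29 (Fisher exact test p = 0.631 and 0.615). In the authors' promoter class 7.12% of listed sites were called, against 5.82% of the others (adjusted p = 0.0402), and 2.15% of listed tiles, against 2.86% of the others (Fisher exact test, adjusted p = 0.345), while 4.03% of sites inside a feature were called (adjusted p = 6.55e-09). On autosomes the promoter share was 7.76%, the inside share 3.53%, and that of sites far from any feature 4.63%, against 6.98% with the X chromosome. The promoter class reached at least 9723 bp from the feature. Of its 114 called sites 15 lay in 1 block of chromosome 21, and the test treats such neighbours as independent. Sites whose closest feature was a 3′ untranslated region were called most often, at 14.6% (Fisher exact test, adjusted p = 1.01e-30). Of those 184 calls 167 lay on the X chromosome, and on autosomes the share was 3.56%. For tiles with that closest feature, all 27 calls were on the X chromosome.

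The X chromosome held the largest share of called site regions, much of it in 1 block. After merging, 14.2% of its listed site regions held a call, against 4.56% elsewhere (chi-square test, adjusted p = 4.61e-81). Of its 448 called sites, 433 were negative, and the median difference of all its listed sites was -1.97 points, against -0.71 on autosomes and -1.01 on the X chromosome outside the block with the most calls. Of the X chromosome, that block held 2364 of 4228 listed sites, 332 of these 448 called sites and 45 of the 49 called tiles. Outside it, 8.32% of the X chromosome's site regions held a call, against 4.56% on autosomes (2-sided Fisher exact test p = 3.48e-08), and for tile regions the shares were 3.28% and 3.57% (Fisher exact test p = 1). Chromosomes 21 (9.84%) and 14 (9.45%) also held more called site regions than the rest, with chi-square adjusted p of 1.59e-05 and 0.00252, and the other 9 of the 12 chromosomes past the threshold held fewer. Among tile regions, chromosomes X (12.9%, adjusted p = 3.17e-05) and 14 (16.5%, Fisher exact test, adjusted p = 4.41e-05) passed, while 5 chromosomes passed when overlapping tiles were counted one by one. Without the block, 6 chromosomes passed for sites (21, X and 14 higher, 15, 10 and 13 lower) and 2 for tile regions, which were 14 and 6, without the X chromosome. With listed sites grouped over 1 kb 8 chromosomes passed, X, 21, 14 and 29 higher (10.9% for 29, chi-square adjusted p = 0.00577) and 10, 15, 11 and 19 lower, and for tiles X and 14 again. A group counted as called when any of its sites was, so group size affects these shares. By merged region, chromosome 29 held a lower share than the rest (4.78% against 6.37%), which did not pass. Neighbouring regions are not independent, with 47 and 22 of the 102 called sites of chromosome 21 and 37 and 16 of the 66 of chromosome 14 in 2 blocks each, and these values describe the chromosomes analysed. For sites, q below 0.05 is not the same p cut on each chromosome, and no common p cut was applied. The called site shares, that of the X chromosome included, may in part reflect the authors' adjustment. Repeated sequence was not checked, so multi-copy sequence was not told apart from single loci in the X chromosome block or elsewhere.

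**Figure D3:**
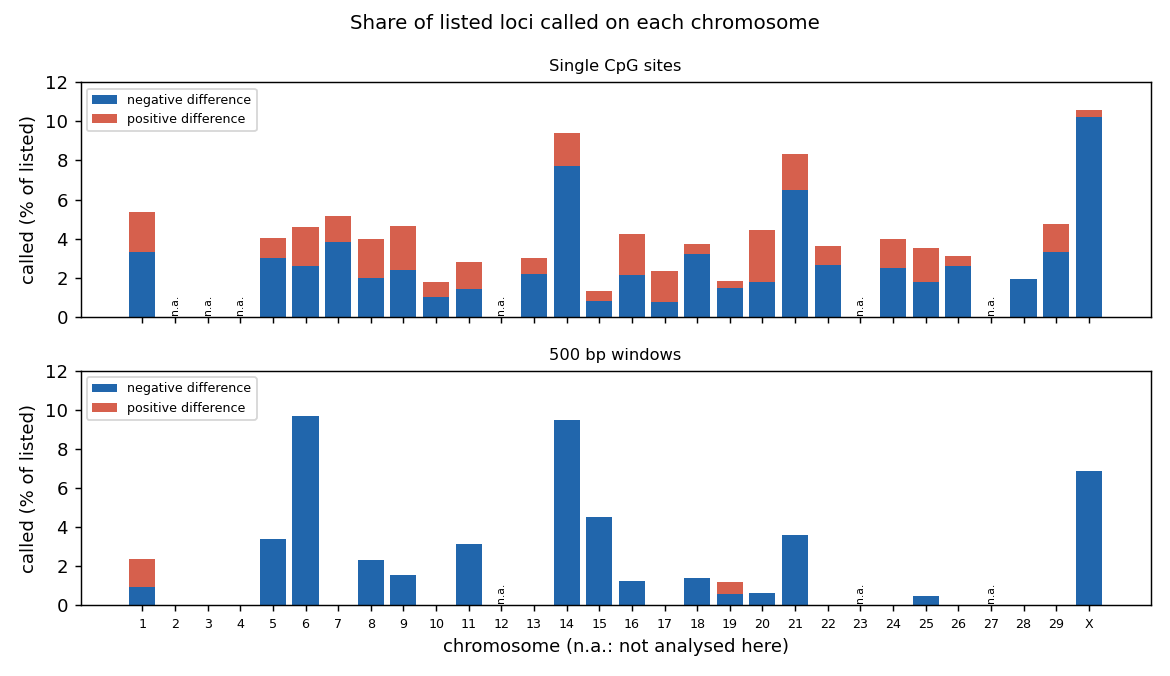
Share of listed loci that were called on each chromosome, in percent, for single CpG sites and tiles; bars are split into negative (blue) and positive (red) differences, and n.a. marks chromosomes not analysed here. The X chromosome has the highest share of sites (10.6%) and chromosome 6 the highest share of tiles (9.71%).

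Few genes of the fixed lists for reproduction, signalling and development lay near a listed locus. Of the 568 list genes 11 lay within 10 kb of a listed tile and 0 were called, against 12 of all 484 genes near a tile (2.48%). With 0 to 2 such members per list, only 3 of the 15 lists could have passed, and only with both members called. For the epididymis, pituitary, spermatogenesis, piRNA, early embryo, TGF-beta and insulin lists no member was near a listed tile. Tiles and sites whose closest feature was a CpG island or a transcript only were assigned to no gene. List genes beside such loci were therefore not counted. Of the 11 genes, 9 had at least 1 tile with q below 0.05, all under 10 points, against 72.3% of all genes near a tile. In the imprinted list, paternally expressed 10 (PEG10) had 2 such tiles, with an extreme of -6.28 points (q = 1.1e-10) inside its 3′ untranslated region in the authors' deposited table. In the comparison list of long axon and synapse genes, CSMD3 had 8 such tiles out of 10 and SLIT2 had 1, with an extreme of -5.92 points in an intron of CSMD3 (q = 5.87e-14) in the authors' deposited table. The somatic check list for blood cells had tiles in introns of IKZF1 (4.97 points, q = 3.25e-06) and CD247 (-1.54 points, q = 6.31e-05) in the authors' deposited table, so its 2 genes had opposite signs. FZD3 of the WNT list (-1.78 points, q = 3.46e-05), OXTR of the placenta list (-1.56 points, q = 0.00380), TET2 of the DNA methylation list (1.65 points, q = 0.0129) and NR5A2 of the steroid list (1.06 points, q = 2.96e-08) differed by less than 2 points in the authors' deposited table. For TET2 (p = 0.0746) and SLIT2 (p = 0.0695) the unadjusted p lay above 0.05 in the authors' deposited table. LHX8 of the ovary list and SMARCA2 of the DNA methylation list had no tile with q below 0.05.

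Among single sites, 89 list genes had a listed site within 10 kb and 2 were called, both in the list of long axon and synapse genes (2 of 27 members, 7.41%, against 6.12% of other genes, 1-sided Fisher exact test p = 0.501, adjusted p = 1). These were intronic sites of the netrin receptor UNC5C (-22.3 points, q = 0.0241) and of the ephrin receptor EPHA6 (-19.4 points, q = 0.0122) in the authors' deposited table, and neither was called at q below 0.01. Adjusted over the list alone, 1 gene of that list had a call (EPHA6), against 2 by the authors' q. In the pituitary list 2 of 3 members had a call adjusted over the list alone, against 0 by the authors' q. These were intronic sites of PRLR (-21.3 points, q = 0.0558) and TACR3 (17.4 points, q = 0.122) in the authors' deposited table. The adjustment over this list covered only 3 sites and was not corrected across the lists, so a short list passes more easily. The PRLR and TACR3 sites are therefore not read as differing between the groups. In each of the other lists no gene had a call adjusted over the list alone, for sites or for tiles. Below the difference threshold, CFAP43 of the spermatogenesis list (-7.87 points, q = 0.0398) and FZD8 of the WNT list (-9.88 points, q = 0.0254) had q below 0.05 in the authors' deposited table. The ovary, steroid, piRNA, imprinted, DNA methylation, early embryo, placenta, TGF-beta, insulin and blood cell lists had members near listed sites, none with q below 0.05, and the epididymis list had none near a listed site.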

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

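Leaving out the block with the most calls, counting both strands of a CpG once, joining calls over 100 kb, 1 vote per block, grouping over 1 kb, subtracting the median of uncalled loci and autosomes alone for the distance to genes were chosen after seeing the data. Apart from the gene lists, 33 of 50 values of the main results under alternatives kept their direction and side of the threshold or stayed within 1.5 times. Called sites numbered 544 at q below 0.01, 230 at q below 0.001, 338 at 20 points, 66 at 30 points and 605 on autosomes, smaller by construction. Called tiles numbered 8 at 20 points and 0 at 30 points, and called tile regions 29 with gaps of 100 kb. The negative share at 30 points was 62.1% of sites, and at 20 points 87.5% of the 8 tiles, neither past the binomial threshold, with fewer loci tested. At 50 kb the odds ratio of a call near a gene was 1.06 for sites and 1.29 for tiles, turned from the main direction and past no threshold, and the cause was not tested. The odds ratio at 10 kb was 0.927 for sites and 0.926 for tiles on autosomes, and 0.788 for tiles without the block with the most calls, each no longer past the threshold, so a lower share near genes was not shown for autosomes. Without that block 6 chromosomes passed for sites in place of 12. With tiles in place of merged regions, 5 chromosomes passed in place of 2, since overlapping tiles count separately. For gene lists the alternatives say little, since few members lay near a tile. Of 27 site loci under the rule, 25 kept their call at q below 0.01 and 20 at q below 0.001. All 8 tile loci kept it at q below 0.001, as did all 203 called tiles, and 1 of the 8 kept it at 20 points. Coverage minimums of 5 and 20, a test without overdispersion, leaving out each sample and matching lists on gene length were not run, since per-sample counts and gene lengths were not analysed here. How far depth limits any call is unknown.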

Other observations

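The tests of gene families and those of the excess of negative differences were chosen only after the result was seen. Some clusters of calls lay near genes that no fixed list covered. On chromosome 21 positions 310455 to 413108 held 22 called sites among 153 listed, 9 negative and 13 positive. Calls there included sites at immunoglobulin heavy variable 4-38-2 (-19.97 points, in an exon) and immunoglobulin heavy variable 4-59 (-10.9 points, in its promoter) in the authors' deposited table. These are antibody variable segments, and they lie in this 1 block. Both of the 2 such genes near a listed site had a call (2-sided Fisher exact test, adjusted p = 0.0125), but the family was picked because of these calls, so the p is no independent evidence. On chromosome 29 positions 5489656 to 5758679 held 22 called sites, 17 of them negative, with 6 near tripartite motif-containing protein 64 and 3 closest to a gene listed as similar to it. Over all tripartite motif genes near a listed site 2 of 10 had a call, which did not pass (2-sided Fisher exact test, adjusted p = 0.244). On the X chromosome all 22 called sites between positions 113614247 and 113622820 were negative, out of 70 listed. Their closest gene is interleukin 1 receptor accessory protein like 1, at least 140920 bp away.

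Genes without a functional name were called more often than named ones. Of 248 such genes near a listed site 34 (13.7%) had a call, against 111 of 2114 others (5.25%; 2-sided Fisher exact test, p = 3.61e-06, adjusted p = 3.61e-05 over 10 tests of gene families). For tiles the counts were 6 of 64 (9.38%) and 6 of 420 (1.43%), with an adjusted p of 0.0104. These tests treat genes as independent, although some called unnamed genes share a block, such as ENSBTAG00000037550 and ENSBTAG00000038660 on the X chromosome. A gene counted as called when any of its loci was, and the number of loci per gene was not matched. Olfactory receptor genes (5 of 57 near a listed site) and zinc finger genes (2 of 47) did not pass, with adjusted p of 0.501 and 1.

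Negative differences outnumbered positive ones among called loci. An offset of equal size in points at all loci is argued against as the whole cause. Bringing the negative share to 60% would need an offset of -6.54 points for sites and -2.67 for tiles. The median of uncalled loci was -0.844 points (95% bootstrap interval over blocks -1.10 to -0.475) for sites and -0.861 (-1.27 to -0.507) for tiles. A shared shift whose size varies with methylation level was not tested and stays open, since levels were not analysed here. The 5 blocks with the most calls, which together hold 46.1% of called sites, do not account for all of it. Without them 72.7% (67.4 to 77.4%) of called sites were negative, but smaller clusters stayed in that count. The size of the excess did depend on clustering, with 60.2% negative (exact 95% interval 54.4 to 65.8%) among the 299 blocks of 1 called site. Of all listed sites with a difference other than 0, 61.2% were negative. For scattered calls an excess over that share was therefore not shown. A difference in fertility between the groups stays open and untested, as do age, breed or library differences between the samples.

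Called sites were crowded into dense stretches. Bins of 10 kb with at least 20 listed sites held 35.9% of listed and 53.2% of called sites. A candidate explanation is more reads per site there, and at differences of 10 to 15 points the median -log10 p was higher in these bins by 0.498 (95% bootstrap interval 0.392 to 0.604). Methylation level also sets p at a given difference, and the levels were not analysed here. Read number alone gives no sign, and 92.9% of called sites were negative in these bins, against 66.5% elsewhere. The dense bins held 560 called sites, and the X chromosome block with the most calls held 332, of which 325 were negative. How much of the contrast in sign rests on that block was not tested.

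Some called sites differed strongly. A sequence difference at the called site alone could change 1 CpG and leave its neighbours as they were. Of the 338 called sites with at least 20 points, 167 had a listed neighbour 2 to 500 bp away, and the median neighbour moved by 35.4% of the called site's difference in the same direction (95% bootstrap interval 21.2 to 40.5%). The interval includes the bound of 25% set for the test, so site-specific and regional differences cannot be told apart over the set. The median was 36.8% in dense bins and 23.2% in the others, and while 83.8% of the 167 sites had neighbours of the same sign (92.4% in dense bins, 73.3% in the others), 26.9% had neighbours that moved by at least 50% of their difference.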
